A study of Trichinella pseudospiralis with 6 samples.

How the data were processed

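Whole-genome bisulfite sequencing (WGBS) and RNA sequencing of Trichinella pseudospiralis were compared over 3 life stages, with 1 library per stage and assay, 6 libraries in all. Per the labels, muscle larvae came from mice 35 days after infection, adults came from the intestine of rats given 8000 larvae each, and newborn larvae were collected every 6 h from adults kept in culture. Adults were taken at 30 h and at 6 days after infection, and the labels do not say which harvest the adult libraries came from. The WGBS and RNA libraries of a stage were matched by stage, not by pool of worms. Groups were taken from the sample titles.

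For WGBS, the authors sheared genomic DNA to which unmethylated lambda phage DNA had been added, per the labels. Alignment used BSMAP 2.73 per the submitters' processing notes, to scaffolds of the study's own long-read assembly; read filters were not given in the sources used here. The deposited call tables list every cytosine of both strands with counts of methylated calls and unmethylated calls, its sequence context of 5 bases, and counts of reads on the opposite strand. The deposited methylation level of each cytosine is a fraction, methylated calls over all calls. The authors' files reduce the unmethylated count where reads of the opposite strand show A in place of G. The names of the opposite-strand count columns are swapped against their values, since the one named for G and A is never above the other, and they were read accordingly. Levels were recomputed here from the deposited counts.

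For RNA, per the labels, poly(A) RNA was fragmented and copied with random primers. HISAT2 2.0.4 was named in the submitters' processing notes; the counting tool and its use of strand were not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart. Deposited counts of uniquely mapped reads per gene are whole even numbers, and were divided by 2 to give read pairs. The deposited RPKM values are read counts scaled by coding length and by all reads counted on genes. Lengths in the authors' other column are coding lengths in bases and equal the summed coding exons of the deposited gene models. A gene not listed for a library was treated as having 0 RPKM.

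The gene models of the series carry identifiers without product names, and no reference annotation was used here. Gene families were therefore found from sequence: the assembly was rebuilt from the 5-base contexts, 12682 gene models were translated, and the proteins were searched with motif patterns and with BLASTP (BLAST 2.17.0, E value 1e-05) against vertebrate and nematode proteins written from general knowledge. In the translated proteins, 9.65% of residues were unresolved. Identity to the query was low in some BLASTP families, such as 20.4% to 33.7% for DNase II-like and 25.2% to 29.5% for major sperm protein-like genes. The lists had been fixed before the data were examined by product-name terms; assigning members by sequence replaced those terms, so each list holds only the families with a usable pattern or query. Lists covered DNA methylation machinery, secreted products, peptidase inhibitors, peptidases, cuticle, germ line, cell cycle, histones, muscle, heat shock, ribosome, glycolysis, mitochondria, transposable elements and nervous system. Kinases, transcription factors, cytoskeleton and mitochondrial carriers were added after the data had been seen. Run on reversed proteins as a control for chance hits, the patterns for MCM helicases matched 2 genes (7 in the real proteins), pyruvate kinase 1 (2), homeobox 2 (50), Kunitz inhibitors 1 (13) and kinases 1 (111), and the others except collagen 0. The collagen pattern, 10 repeats of G-x-x, reads the same in reversed proteins, so that control could not test it, and its genes are collagen-like by this repeat only.

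Methylation levels are methylated calls over calls per context, with exact Clopper-Pearson 95% intervals. A cytosine with at least 10 calls was called methylated by a 1-sided binomial test against the rate of the lambda DNA of its library, with Benjamini-Hochberg adjustment at 0.01. CG dyads (both strands summed) with at least 10 calls in both libraries were compared by a 2-sided Fisher's exact test with Benjamini-Hochberg adjustment at 0.05 and a level difference of at least 25 percentage points. This test compares 2 libraries, not the stages. On simulated dyads with the depths of muscle larvae and adults, it recovered 24.1% of differences of 40 points and 67.0% of differences of 60 points over 1022863 dyads. For adults against newborn larvae these shares were 25.8% and 73.9% over 1062401 dyads, and for muscle larvae against newborn larvae 23.8% and 64.2% over 999111 dyads. In these simulations few dyads differed and the lower library was little methylated. The shares therefore do not carry over to dyads methylated in both libraries, or to pairs with many differing dyads. Levels of gene bodies and of 1 kb upstream windows needed at least 5 such dyads, and a difference of 10 points was the size rule. Features were coding exons, introns, 1 kb flanks and sequence between genes.

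Expression was compared as log2((RPKM + 1)/(RPKM + 1)), which understates changes of low genes. A gene passed the size rule with an absolute value of at least 2 and at least 5 RPKM in the higher library, and a stage-biased gene passed it against both other libraries. No p-value was computed across genes. A list of at least 5 genes with 1 RPKM in any library was described by its median and by the percentile of that median among 10000 random lists of equal size matched on mean expression in 10 bins, with a bootstrap interval over members from 2000 draws. Spearman's rho between level and expression was computed across genes, with 200 bootstrap draws. Intervals of RPKM ratios of single genes are exact binomial intervals on read pairs.

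The rule for named genes, written before the data were examined, was: the 2 genes by identifier with the largest expression difference each way per pair of stages, since products had no names; the 3 genes with the largest gain and loss of gene body level among those with at least 10 dyads; every member of the DNA methylation machinery; and up to 4 members of each other list.

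Alternatives covered call minimums of 5 and 20, other error rates, thinning to equal calls, single strands, 2 kb flanks, per-site means, scaffolds of at least 100 kb, a pseudocount of 0.1, no RPKM minimum, rescaling to a common median ratio, shares of summed RPKM, and restriction to expressed genes. After the data had been seen, CG dyads near non-CG calls and genes with high non-CG levels were also left out. Scripts used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Numba 0.67.0, PyArrow 21.0.0 and Matplotlib 3.10.9. Duplicate copies of the expression tables were left out. Depth limits precision: mean calls per cytosine were 10.6 in adults, 7.44 in muscle larvae and 8.28 in newborn larvae, and read pairs on genes numbered 10069975, 8147734 and 9988366.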

Results

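DNA methylation and transcript levels were measured in adults, muscle larvae and newborn larvae of Trichinella pseudospiralis, a parasitic nematode whose newborn larvae migrate from the intestine to host muscle. The design asked how single-base methylation and gene expression differ between these 3 life stages. Each stage had 1 WGBS library and 1 RNA library, so there was no replicate check on any difference below. The WGBS libraries held 230202562 cytosine calls in adults, 161413008 in muscle larvae and 179619342 in newborn larvae, over an assembly of 2746 scaffolds and 68.9 Mb. The RNA libraries listed reads on 9636, 9746 and 9613 of 12682 genes, respectively. Intervals cover counting error only, because PCR reads without molecular identifiers are not independent molecules. The files pair no gene names with identifiers, so families are given by their sequence.

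CG methylation was present in adults and muscle larvae and lay at the level of the unmethylated lambda spike-in in newborn larvae. The CG level was 5.78% in adults (5.77 to 5.79), 8.21% in muscle larvae (8.20 to 8.22) and 0.479% in newborn larvae (0.477 to 0.481). CG cytosines of the lambda DNA gave 0.338%, 0.351% (0.217 to 0.536) and 0.512% (0.387 to 0.664) in the same order. Over the 995487 CG dyads with at least 10 calls in all 3 libraries, the levels were 5.62%, 8.05% and 0.475%. CHG levels were 0.382%, 0.594% and 0.413%, and CHH levels were 0.627%, 1.31% and 0.668%. The CHH level of lambda DNA was 0.371% (0.300 to 0.454), 0.513% (0.375 to 0.686) and 0.689% (0.568 to 0.827).

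**Figure D1:**
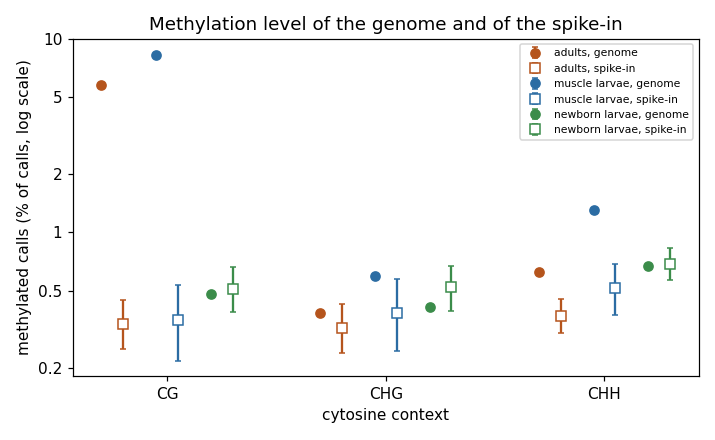
Methylated calls as a percent of calls (log scale) per cytosine context in the genome (filled circles) and in the lambda spike-in (open squares) of each library, with exact 95% binomial intervals. The genome of newborn larvae lies at 0.479% in CG, within the interval of its spike-in, while adults and muscle larvae lie at 5.78% and 8.21%.

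Sequence between genes carried the highest CG level in both methylated stages. It reached 11.1% in adults and 15.8% in muscle larvae, against 4.43% and 6.14% in coding exons, 4.44% and 6.20% in introns, and 4.61% and 6.46% in 1 kb upstream flanks. Downstream flanks had 5.73% and 7.92%. Within gene bodies the level rose from 3.58% in the first of 20 bins to 4.99% in the last in adults, and from 5.10% to 6.89% in muscle larvae. In newborn larvae the 5 features lay between 0.436% and 0.501%. Methylated CG cytosines numbered 236478 of 1843638 tested in adults (12.8%), 161418 of 965236 in muscle larvae (16.7%) and 307 of 1243213 in newborn larvae. Most were partly methylated, with a median level of 28.0% in adults and 30.8% in muscle larvae. Of the 904180 CG cytosines tested in both of these libraries, 103790 were called in both, against 20791 for independent lists.

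Candidate enzymes of DNA methylation were low in newborn larvae. The gene TP07589 (Scaf38, 291402 to 298252, 13 coding exons) was the only one assigned to DNMT3, the enzyme family that places new methyl groups on DNA. TP07589 had 88.1 RPKM in adults, 54.7 in muscle larvae and 6.53 in newborn larvae. TP11965 (Scaf87, 69190 to 70628, 9 coding exons), the only gene assigned to DNMT2, a family best known for methylating transfer RNA, had 27.9, 31.6 and 2.01 RPKM. Both passed the size rule for adults over newborn larvae (log2 of 3.56 and 3.26) and for muscle larvae over newborn larvae (2.89 and 3.44). Between muscle larvae and adults the values were -0.68 and 0.18, and the latter turned to -0.03 after rescaling to a common median ratio. Each gene was assigned to its best query only, and none of the 12682 translated models was assigned to DNMT1, the maintenance enzyme. With queries written from general knowledge and 9.65% of residues unresolved, this search cannot show that the enzyme is absent. The RPKM ratio of adults to newborn larvae had a log2 of 3.75 for TP07589 (3.47 to 4.05, from 1496 and 110 read pairs) and 3.80 for TP11965 (3.12 to 4.55, from 266 and 19 pairs).

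Muscle larvae against adults: genes with collagen-like repeats, put in the cuticle list by that repeat only, had the list median furthest from 0, with 18 of 36 higher in adults and 0 higher in muscle larvae by the size rule. TP07345 had 1772 RPKM in adults and 0.880 in muscle larvae (log2 of -9.88), and TP01130 had 3873 and 34.8 (log2 of -6.76). The median log2 of the list was -2.01 (-3.59 to -0.35), lower than all 10000 matched random lists. TP07454 and TP02440, which have no family assignment, were the most raised genes of muscle larvae, from 2.69 to 2001 RPKM (log2 of 9.08) and from 5.71 to 2645 RPKM (log2 of 8.62). TP07454 lies on Scaf37 (115060 to 117294) beside TP07455, a DNase II-like gene that went from 0.957 to 52.5 RPKM. TP04450, also without a family, went from 608 RPKM in adults to 0.435 in muscle larvae.

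Other families split between these stages. Major sperm proteins drive the movement of nematode sperm. The 13 genes assigned here were only 25.2% to 29.5% identical to the query, so a role in sperm is not shown. Among them, TP09700 had 93.1 RPKM in adults and 6.20 in muscle larvae (log2 of -3.71). Of 26 genes of the germ line list, 4 were higher in adults. That list holds 19 DEAD-box helicases, a family used in many cells, beside the major sperm protein-like genes. Of 41 histone genes, 18 had at least 1 RPKM in any library. The RNA was poly(A) RNA, so histone transcripts without a poly(A) tail would be missed. Of the 18, 4 were higher in adults, among them TP05407, an H2A gene (log2 of -4.90). Genes matching the pattern of MCM helicases, which open DNA for replication (7 genes, against 2 in reversed proteins), included TP09489 with 92.9 and 25.9 RPKM, and the cell cycle list had a median of -1.05 (percentile 0.43) with 0 of 8 genes past the rule. The nuclear receptors TP06168 and TP02395 were higher in muscle larvae (log2 of 4.53 and 3.63), as were the Kunitz inhibitor TP03132 (3.78) and the myosin TP05010, with 102 RPKM against 14.5 in adults. The astacin-like peptidase TP10094 (-6.80), the Kunitz inhibitor TP11245 (-4.62) and the papain-like peptidase TP06832 (-3.93) were higher in adults. Peptidases went both ways: of 25 genes, 2 were biased to adults and 1 to muscle larvae against both other libraries. Medians were -0.61 for peptidase inhibitors (percentile 0.955), -0.32 for peptidases (1.95), -0.40 for histones (1.57), -0.68 for muscle (1.09), -0.12 for the germ line (6.71) and -0.07 for secreted products (5.93).

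Over all genes, 610 were higher in muscle larvae and 618 in adults. After rescaling to a common median ratio these counts were 459 and 707. Spearman's rho between the RPKM of the pair was 0.825 across genes, which are not independent replicates. Over genes with at least 1 RPKM in all 3 libraries, the deposited RPKM carried a median log2 of 0.22 for muscle larvae over adults, 0.30 for adults over newborn larvae and 0.52 for muscle larvae over newborn larvae. List percentiles are relative to matched genes of the same libraries and so to these shifts. Members of a list are related genes, some of them close neighbours, and are not independent. Random lists and bootstrap draws take genes singly, so percentiles and list intervals may overstate how far a list stands apart.

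Methylation was higher in muscle larvae than in adults over most gene bodies. Of 9651 measured genes, 75.9% had the higher level in muscle larvae, 284 by at least 10 points, and 8 were higher in adults by that margin. Without the 1017 genes with a non-CG level of 2% or more, a limit chosen after the data had been seen, these counts were 180 and 7. TP09960 (Scaf59, 206818 to 207165, 1 coding exon) had 19.7% in adults and 46.4% in muscle larvae, and TP04319 (Scaf2, 36446 to 37081, 1 coding exon) had 12.1% and 39.0%. Their non-CG levels in muscle larvae were 2.44% and 0.71%, so TP09960 is among the 1017 genes left out at 2%. Their mean calls per cytosine there were 23.8 and 28.8, against 7.44 over the library. TP05846 (Scaf26, 332335 to 332664, 1 coding exon), a match to the glycolytic enzyme GAPDH, had 0.17% and 39.8% in CG, but also 0.14% and 45.0% in non-CG cytosines. Upstream windows were higher in muscle larvae for 301 genes and in adults for 2. Fisher's exact test on reads found 1414 dyads higher in muscle larvae and 54 higher in adults among 1022863 tested, at an adjusted threshold of 0.05 by Benjamini-Hochberg. At equal calls the counts were 634 and 5, and on single strands 151 and 0. The 1414 had a median level of 22.6% in adults. On simulated dyads of this depth the test recovered 24.1% of differences of 40 points, but there the lower library was little methylated. That share therefore does not measure how many differences were missed here.

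Adults against newborn larvae: DNase II-like genes, an expanded family of secreted nucleases in Trichinella, were higher in newborn larvae for 12 of 20 genes and higher in adults for 0. TP09738 and TP09740, close neighbours on Scaf56, had 0.901 and 0.777 RPKM in adults and 3404 and 2626 RPKM in newborn larvae (log2 of -10.81 and -10.53). TP00805 and TP10361, without a family, had 1.68 and 2.19 RPKM against 7569 and 6289 (log2 of -11.46 and -10.95). The secreted list had a median of -0.83 (-2.43 to 0.09, percentile 0.23). Of its 20 trypsin-like members, 6 were higher in adults, such as TP01385 (6.02) and TP10202 (5.85), and 4 in newborn larvae. Among glycolysis genes, the aldolase gene TP01607 had 4601 RPKM in newborn larvae against 606 in adults (log2 of -2.92), the lactate dehydrogenase gene TP06794 had 1322 against 277 (-2.25), and TP02127 went the other way with 3.39 against 11.8 (1.54). TP02127 matched the pyruvate kinase pattern, which found 2 genes and 1 in reversed proteins. The list median was -1.87 (-2.25 to -1.20, percentile 0.57), with 3 of 7 genes past the rule. Cys-loop receptors, which are ligand-gated ion channels of nerve and muscle, had a median of -1.49 (-1.92 to -0.86, percentile 0.23) and 5 of 18 genes higher in newborn larvae, the lowest being TP03591 (-3.14), while TP01812 was higher in adults (2.04).

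The cell cycle, germ line, collagen-like and peptidase lists had medians toward adults, with members both ways. Of 7 MCM-pattern genes, 4 were higher in adults, TP06417 (log2 of 3.98) and TP09489 (3.49) being the furthest, while TP04570 was at -0.55, and the cell cycle list had a median of 2.25 (1.16 to 3.41, percentile 99.7). The germ line list had a median of 1.09 (percentile 98.8), with 5 of 7 major sperm protein-like genes and 2 of 19 DEAD-box helicases higher in adults and 0 in newborn larvae, including TP09700 (5.67) and the DEAD-box helicase TP11444 (4.60, from 87.8 to 2153 RPKM). Collagen-like genes had a median of 1.19 (percentile 99.6), with 15 of 36 higher in adults and 2 in newborn larvae, and TP07344 reached 1784 RPKM against 0.596 (log2 of 10.13). Peptidases had a median of 1.25 (percentile 99.2), with 10 of 24 higher in adults and 0 in newborn larvae, led by the papain-like gene TP00150 (7.27) and the aspartic peptidase TP07295 (5.52), while the astacin-like TP08674 was at -1.43. Histones, measured in poly(A) RNA only, had a median of 1.21 (percentile 98.6), with 7 of 18 higher in adults. Heat shock genes included TP01493, an HSP90 gene (2.77), and TP00506, an HSP70 gene with 2357 RPKM against 356, and 2 of 5 were past the rule at a median of 0.44 (percentile 63.1). Medians were 0.69 for mitochondria (percentile 71.3, 2 of 17 higher in adults), -0.55 for muscle (11.6, 1 of 9 higher in adults, -0.86 after rescaling) and -0.37 for peptidase inhibitors (10.4, 2 and 3 of 15).

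Over all genes, 1455 were higher in adults and 1076 in newborn larvae. Rescaling to a common median ratio gave 1194 and 1368. Spearman's rho across genes was 0.685. The list medians above 0 for this pair stayed above 0 under the rescaled values and under shares of summed RPKM.

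Gene bodies methylated in the adult library had low levels in the newborn library. TP11273 (Scaf75, 74440 to 74739, 1 coding exon) had 35.6% and 0%, TP06590 (Scaf3, 1388490 to 1389064, 2 coding exons) 32.0% and 0%, and TP07788 (Scaf4, 372792 to 374099, 4 coding exons) 29.9% and 0%. In the same order, non-CG levels in adults were 2.39%, 1.51% and 1.24%, the first past the 2% limit used above. In total, 1175 of 9792 genes were higher in adults by at least 10 points and 4 in newborn larvae. Of these, TP05846 had 13.2% CG and 14.3% non-CG in newborn larvae, and TP08231 (Scaf41, 25678 to 30594) had 12.6% CG and 70.5% non-CG, with 1.82% CG and 10.997% non-CG in adults. Upstream windows gave 1170 genes and 1 gene. Fisher's exact test on reads with Benjamini-Hochberg adjustment found 31584 dyads higher in adults and 57 higher in newborn larvae among 1062401. At equal calls the counts were 16942 and 33, and among dyads with non-CG levels of at most 5% nearby, a limit chosen after the data had been seen, 30354 and 1.

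Muscle larvae against newborn larvae: the DNase II-like family again stood apart, with 15 of 20 genes higher in newborn larvae and 2 in muscle larvae. TP09740 had a log2 of -10.68 and TP09738 of -10.56, whereas TP07455 of the same family was higher in muscle larvae (5.60). The unassigned genes TP02440 (10.70) and TP07454 (9.62) led the genes of muscle larvae, and TP00805 (-10.84) led those of newborn larvae. Secreted products had a median of -1.44 (-3.05 to -0.23), lower than all 10000 matched lists. Papain-like peptidases, a family of lysosomal and secreted enzymes, were higher in muscle larvae for 7 of 11 genes, including TP11549 (5.60), and 3 of 3 aspartic peptidases were too, including TP07295 (6.30). Of the astacin-like peptidases, 0 were higher in muscle larvae and 3 in newborn larvae, including TP02458 (-2.38) and TP10094 (-2.18). The peptidase list had a median of 1.22 (percentile 99.0).

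The medians of glycolysis (-1.56, percentile 0.495) and cys-loop receptors (-1.04, percentile 0.06, and -1.52 after rescaling) were again low among matched lists. Cell cycle genes had a median of 1.47 (percentile 97.0), with 2 of 8 past the rule, among them TP06417 at 2.88. Collagen-like genes had a median of -0.61 (percentile 0.01), with 9 of 36 higher in newborn larvae, such as TP08612 (-4.40), and 4 higher in muscle larvae, such as TP07342 (7.30). Medians were 0.68 for the germ line (percentile 73.2, 0.16 after rescaling), 0.81 for histones (81.8, 0.31 after rescaling), 1.32 for heat shock (84.8, 0.79 after rescaling), 0.88 for mitochondria (79.8, 0.37 after rescaling), -0.53 for muscle (4.45) and -0.46 for peptidase inhibitors (1.54). Ribosomal proteins had 3 measured members, with log2 values of 1.55, 1.69 and 1.59 for muscle larvae over newborn larvae, 0.70, 1.03 and 0.51 for muscle larvae over adults, and 0.85, 0.67 and 1.08 for adults over newborn larvae, for TP02258, TP06581 and TP12285. Of 4 retroelement genes with expression, TP06077 had 17.2, 8.13 and 298 RPKM in adults, muscle larvae and newborn larvae and TP06006 had 7.11, 43.3 and 7.82. The 4 had a median of 0.71 for muscle larvae over adults, -1.25 for adults over newborn larvae, and 0.38 for muscle larvae over newborn larvae, which turned to -0.14 after rescaling.

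Kinases and transcription factors, families added after the data had been seen, had members both ways. Kinases had 0.10 for muscle larvae over adults, 0.50 for adults over newborn larvae and 0.37 for muscle larvae over newborn larvae (percentiles 18.1, 78.8 and 16.9), of which the first and the last turned to -0.11 after rescaling. Transcription factors had 0.17, which turned to -0.03 after rescaling, -0.26 and -0.10 (percentile 32.0, percentile 0.12, and lower than all 10000 matched lists), and the last was -0.63 after rescaling. TP02799, a homeobox gene, had 865 RPKM in adults and 6.71 in newborn larvae. TP10973, a tubulin gene and the only cytoskeleton gene, had 1081, 868 and 428 RPKM. For muscle larvae over adults, glycolysis had 0.31 (percentile 42.5), heat shock 0.47 (60.4), mitochondria 0.34 (69.6) and the nervous system 0.38 (65.7). Over all genes of muscle larvae against newborn larvae, 1112 were higher in muscle larvae and 657 in newborn larvae, and rescaling gave 719 and 1031. Spearman's rho across genes was 0.768.

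Gene body methylation was higher in muscle larvae than in newborn larvae by at least 10 points in 1848 of 9635 genes and lower in 0. TP07462 (Scaf37, 156143 to 157130, 3 coding exons) had 56.8% against 1.74%, TP11273 51.8% against 0%, and TP06590 46.6% against 0%. In the same order, non-CG levels in muscle larvae were 2.81%, 4.80% and 1.63%, so TP07462 and TP11273 lie past the 2% limit. Upstream windows gave 1779 genes and 0 genes. Fisher's exact test on reads with Benjamini-Hochberg adjustment found 61575 dyads higher in muscle larvae and 3 higher in newborn larvae among 999111, and 39554 and 0 at equal calls.

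**Figure D2:**
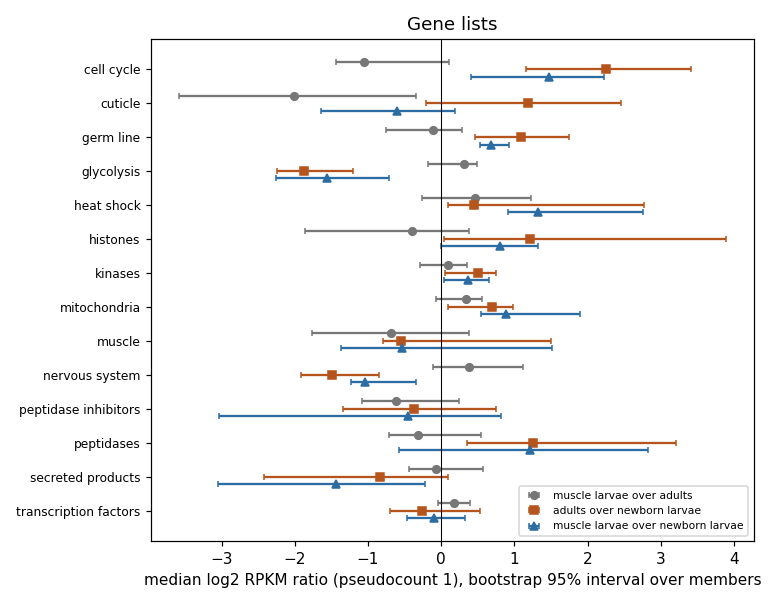
Median log2 RPKM ratio of each gene list (x axis) for the 3 pairs of stages, with bootstrap 95% intervals over members. Cuticle lies at -2.01 for muscle larvae over adults and glycolysis at -1.87 for adults over newborn larvae; kinases turn from 0.10 and 0.37 to -0.11, and transcription factors from 0.17 to -0.03, after rescaling to a common median ratio.

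Stage-biased genes, past the size rule against both other libraries, numbered 479 in adults, 251 in muscle larvae and 480 in newborn larvae. Those of newborn larvae held 24.5% of the summed RPKM of their library, against 16.9% in adults and 7.93% in muscle larvae. Collagen-like genes supplied 14 of the adult genes and DNase II-like genes 12 of those of newborn larvae and 2 of those of muscle larvae. Rescaling raised the newborn count to 733.

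Weakly expressed genes carried more CG methylation than strongly expressed genes in adults and muscle larvae. The median gene body level fell from 6.72% in adult genes under 1 RPKM to 1.14% in the highest expression quartile, and from 9.09% to 1.84% in muscle larvae. Upstream windows ran from 6.48% to 0.853% and from 8.65% to 0.926%. In newborn larvae the gene body medians were 0.378% and 0.423%. Spearman's rho across genes between RPKM and gene body level was -0.381 (-0.398 to -0.363) in adults, -0.375 (-0.392 to -0.357) in muscle larvae and 0.0895 (0.0694 to 0.108) in newborn larvae. With upstream windows it was -0.412, -0.439 and -0.0434. Genes are not independent replicates, and no p-value is given. The CG level of newborn larvae lay at that of the spike-in, so rho there ranks levels not told apart from background. Non-CG levels of newborn coding exons, with 9 or more G within 40 bases, also rose with newborn RPKM. They were 0.444% under 10 RPKM and 0.743% at 1000 RPKM or more.

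**Figure D3:**
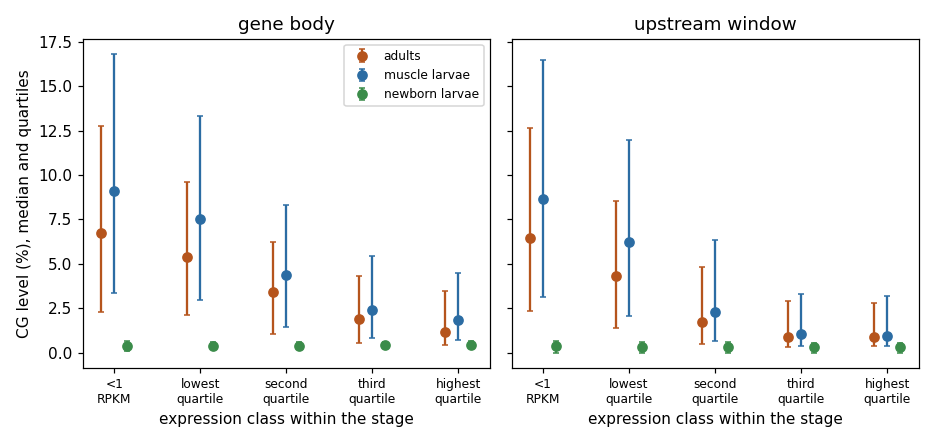
Median CG level (percent, with quartiles) of gene bodies and 1 kb upstream windows by expression class within each stage. Adults run from 6.72% to 1.14% and muscle larvae from 9.09% to 1.84% in gene bodies, while newborn larvae lie at 0.378% and 0.423%.

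DNase II-like genes had a median gene body level of 11.3% in adults and 13.2% in muscle larvae, and 0.45% in newborn larvae. Across genes, the change in gene body level and the change in log2 expression had a rho of -0.0231 (-0.0449 to -0.00149) for muscle larvae minus adults, -0.0636 (-0.0873 to -0.0440) for adults minus newborn larvae and -0.138 (-0.161 to -0.116) for muscle larvae minus newborn larvae. For upstream windows these were 0.0120, -0.0491 and -0.0953. Among genes of at least 1 RPKM, the values were -0.118 and -0.0842 for adults minus newborn larvae and -0.192 and -0.137 for muscle larvae minus newborn larvae. Since gene bodies of newborn larvae had a median of 0.398%, differences from that library are close to the level of the other stage. Adult-biased genes had a median body level of 7.36% in adults and newborn-biased genes 6.04%, against 3.05% for all genes.

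CHH calls varied with the number of G around them in all 3 libraries, and with local CG methylation in adults and muscle larvae. Where no G lay within 40 bases on the strand of the cytosine, the CHH level was 28.5% in adults, 91.3% in muscle larvae and 89.7% in newborn larvae. With 9 or more G it was 0.554%, 0.888% and 0.459%. From windows of 500 bases with a CG level under 2% to those of 30% or more in another library, CA cytosines gained 1.53 points in adults and 2.42 points in muscle larvae, CT cytosines gained 0.802 and 1.496 points, and CC cytosines gained 0.132 and 0.159 points. In newborn larvae the differences were -0.0872 points for CA, -0.0754 for CT and -0.105 for CC.

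**Figure D4:**
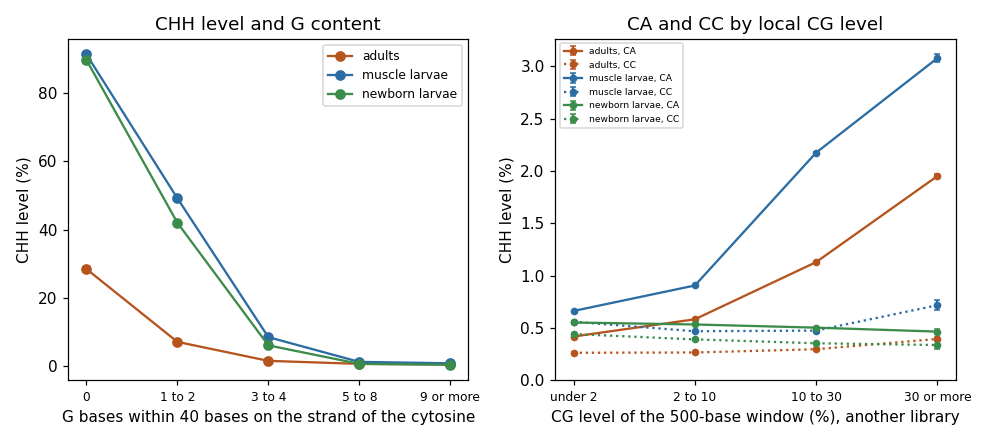
CHH level (percent) by the number of G within 40 bases (left) and by the CG level of the 500-base window in another library, for CA and CC cytosines with exact 95% intervals (right). Levels without G reach 91.3% in muscle larvae, and CA rises with CG level in adults and muscle larvae, by 1.53 and 2.42 points.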

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

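All tests in this part were chosen after the results they bear on had been seen.

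Reads on the opposite strand of a cytosine, which the comparisons above use only through the deposited correction of unmethylated counts, differed from the assembly in 80% or more of at least 10 reads at 1140 cytosines of adults (of 12263182), 1311 of muscle larvae (of 6899555) and 1032 of newborn larvae (of 8152618). In lambda DNA 0 of 32 such cytosines differed in adults and 0 of 32 in newborn larvae, and none had the depth in muscle larvae. With genome shares of 0.0093% in adults and 0.0127% in newborn larvae, so few lambda cytosines cannot serve as a control. Of 5618008 cytosines with that depth in all 3 libraries, 920 differed in at least 1 and 250 in all 3.

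The CG level of newborn larvae, close to the spike-in, lay far below that of adults and muscle larvae, at 0.479% against 5.78% and 8.21%. Different covered cytosines are argued against, because the level stayed at 0.475% over the dyads measured in all 3 libraries, where adults had 5.62%. Conversion of methylated cytosines along with unmethylated ones in that library alone stays open, since lambda DNA is unmethylated and cannot show it. Outside G-poor sequence only 7 CG cytosines of newborn larvae kept 80% or more of at least 10 calls, against 2160 in adults and 7165 in muscle larvae, too few to exclude it. A life stage with little CG methylation remains the biological explanation, untested because stage and library cannot be told apart with 1 library each.

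Coding exons of strongly expressed genes carried non-CG calls in muscle and newborn larvae. Incomplete conversion that strikes all sequence equally is argued against by genes of 1000 RPKM or more in muscle larvae. Introns, measured in 60 of these genes, had 0.727% (0.507 to 1.12) there, and coding exons, measured in 72, had 2.74% (1.77 to 4.12). The exon value thus includes genes without measured introns, and incomplete conversion confined to such genes stays open. RNA of the newborn worms is argued against in their own library. Newborn-biased genes of 1000 RPKM or more had 0.525% (0.433 to 0.658) there and other genes of that expression 1.10% (0.742 to 1.81). Genes of 1000 RPKM or more in muscle larvae had 1.84% (1.18 to 2.68) in newborn coding exons (72 genes) and 0.489% (0.383 to 0.704) in introns (60 genes). In the muscle larva library, exons at that threshold had 2.74% by its own RPKM, 2.13% by adult and 1.40% by newborn RPKM. Those intervals overlapped. RNA of muscle larvae was not tested as a cause in either library. Among genes of 100 RPKM or more in muscle larvae, the 12 that were at least 60% identical to a vertebrate protein had 4.92% (2.22 to 10.8) and the others 0.942% (0.886 to 1.01), and without the gene of the highest level the value was 3.33% (1.83 to 5.63). These sets were not matched on expression, and the exon level rose from 0.898% (0.858 to 0.942) at 100 to 1000 RPKM to 2.74% at 1000 or more. The comparison thus cannot tell conservation from expression. Unconverted reads of another organism placed on conserved genes stay a candidate explanation, which would cover TP05846 but leaves TP08231 open. TP08231 had 10.997% non-CG in adults, 80.9% in muscle larvae and 70.5% in newborn larvae and matched none of the proteins searched. Its CG level in newborn larvae, given above, was far below its non-CG level there. Levels of single genes used all non-CG cytosines. Reads placed on the wrong strand in G-poor sequence were therefore not set apart for TP08231 and were not tested as its cause. No biological explanation was tested.

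CHH calls exceeded the spike-in in muscle larvae and in adults, where they were 0.627% against 0.371% (0.300 to 0.454). Reads placed on the wrong strand in G-poor sequence may supply part of them, since the level reached 91.3% in muscle larvae and 28.5% in adults where no G lay within 40 bases. They are not the whole excess, because with 9 or more G it was still 0.888% in muscle larvae, above the interval of lambda CHH (0.375 to 0.686), and 0.554% in adults. In the part that follows CG methylation, CA gained 2.26 points more than CC in muscle larvae (1.88 to 2.65) and 1.40 more in adults (1.32 to 1.48). In newborn larvae the difference was 0.018 (-0.027 to 0.069). Incomplete conversion that strikes CA and CC equally is argued against as the source. However, CHH cytosines of lambda DNA were themselves uneven. CA and CC had 0.514% (0.389 to 0.667) and 0.229% (0.138 to 0.358) in adults, and 0.780% (0.523 to 1.12) and 0.392% (0.196 to 0.701) in muscle larvae. Incomplete conversion that strikes CA more than CC therefore stays open. CT gained 1.496 and 0.802 points in muscle larvae and adults, so methylation of CA and CT next to methylated CG remains a hypothesis found and tested on the same data.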

How the results depend on the processing

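Alternatives were fixed before the data were examined, except those leaving out sequence with non-CG calls, which were chosen after seeing the data. No paired analysis was possible because each stage had 1 library per assay. Of 324 alternative values for results other than named genes, the ones below moved beyond the interval of the result or, for counts, by over 1.5 times; intervals of levels are so narrow that small shifts count. Where no reason is named, the cause was not tested.

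With at least 10 calls per cytosine, CG levels were 5.66% in adults, 8.56% in muscle larvae and 0.460% in newborn larvae, CHG 0.377%, 0.556% and 0.394%, and CHH 0.607%, 1.34% and 0.637%. As means of per-site levels, CG was 5.01%, 7.02% and 0.470%, CHG 0.360%, 0.551% and 0.407%, and CHH 0.566%, 1.05% and 0.587%. On scaffolds of at least 100 kb, CG was 4.77%, 6.70% and 0.474%, CHG 0.351%, 0.556% and 0.416%, and CHH 0.553%, 1.21% and 0.683%. The order of the stages in CG held in each.

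As means of per-site levels, features of adults were 4.38% in exons, 4.28% in introns, 4.29% upstream, 5.34% downstream and 8.42% between genes. Muscle larvae had 5.95%, 5.94%, 6.01%, 7.48% and 12.4%, and newborn larvae 0.431%, 0.428%, 0.436% and 0.457% from introns on. With 2 kb flanks, upstream, downstream and intergenic levels were 4.88%, 6.65% and 13.7% in adults and 6.93%, 9.44% and 19.1% in muscle larvae, and newborn larvae had 0.430% upstream and 0.521% between genes.

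Methylated cytosines fell with a minimum of 20 calls, which tests fewer sites: CG to 79797 in adults, 69834 in muscle larvae and 114 in newborn larvae, CHG to 1184 in muscle larvae and 108 in newborn larvae, and CHH to 14724, 18979 and 2657. With a minimum of 5 calls newborn larvae had 518 CG, 587 CHG and 13784 CHH. At a false discovery rate of 0.05, CHG was 1905 in adults and 3393 in muscle larvae. With an error rate of 0.01, adults had 326 CHG and 18507 CHH, muscle larvae 1046 CHG, and newborn larvae 171 CG and 223 CHG. Thinned to 10 calls, adults had 161 CHG and 17944 CHH, muscle larvae 1357 CHG and 23170 CHH, and newborn larvae 186 CG.

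Thinning to equal calls, which lowers power, gave 634 dyads higher in muscle larvae and 5 in adults, 16942 in adults and 33 in newborn larvae, and 39554 in muscle larvae and 0 in newborn larvae. Single strands gave 151 and 0 for muscle larvae against adults, 28 higher in newborn larvae than in adults and 0 higher in newborn than in muscle larvae. A difference of 10 points gave 124 dyads higher in adults than in muscle larvae and 7 higher in newborn than in muscle larvae, and that last count was 12 with 5 calls and 1 with 20 calls. Away from non-CG calls, 1 dyad was higher in newborn larvae than in adults and 0 than in muscle larvae.

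Gene bodies higher in adults than in muscle larvae numbered 0 with 10 dyads and 16 with dyads of 5 calls, and upstream windows 0 and 8. Those higher in newborn larvae than in adults numbered 2 bodies and 0 windows with 10 dyads and 0 windows with 5 calls. Leaving out 1017 genes with a non-CG level of 2% or more, the first limit tried, gave 180 bodies higher in muscle larvae than in adults in place of 284, and 0 higher in newborn larvae. A limit of 5%, added once those values were known because CA and CT calls follow CG methylation, left out 183 genes and gave 256 and 0.

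Rescaling to a common median ratio gave 719 genes higher in muscle larvae than in newborn larvae and 1031 the other way, and 733 newborn-biased genes. For muscle larvae over newborn larvae it turned kinases to -0.11, and gave 0.16 for germ line, 0.79 for heat shock, 0.37 for mitochondria, -1.52 for the nervous system and -0.63 for transcription factors; muscle was -0.86 for adults over newborn larvae. Of 618 alternative values for named genes, 595 kept their side of the size rule. None past the rule could change direction, because a pseudocount cannot change the sign and the rescalings shift log2 values by much less than 2.

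Among genes of at least 1 RPKM, rho with body and upstream levels was -0.338 and -0.308 in adults, -0.332 and -0.359 in muscle larvae, and -0.0230 upstream in newborn larvae. For changes it was -0.118 and -0.0842 for adults minus newborn larvae and -0.192 and -0.137 for muscle minus newborn larvae.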

Other observations

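The comparisons in this part were chosen after the data had been seen and are given as values. Homeobox genes, which encode regulators of body pattern, were among the more methylated families. Their median gene body level was 8.33% in adults and 11.5% in muscle larvae, against 3.05% and 3.92% over all genes, and 24 and 31 of 50 genes had at least 10%. Their median log2 expression was -1.18 (-1.41 to -0.64) for adults over newborn larvae and -1.17 (-1.48 to -0.38) for muscle larvae over newborn larvae, with 12 and 10 of 50 genes higher in newborn larvae and 7 and 4 lower there, such as TP04522 (6.18 and 5.34). Astacin-like peptidases had 8.73% and 10.4%, and protein kinases 2.22% and 2.81%.

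Genes listed in none of the 3 RNA libraries had a median body level of 7.51% in adults (605 measured genes) and 9.01% in muscle larvae (492 measured genes), and 0.31% in newborn larvae. Among CG dyads at 20% or more in adults or muscle larvae, 74.3% of 137420 were higher in muscle larvae, with medians of 22.2% and 30.0%. Spearman's rho between the levels of these libraries was 0.306 over those dyads and 0.649 over the 995487 common dyads, most of them little methylated. Between adults and newborn larvae it was 0.0623 and 0.0766. Of the 307 CG cytosines called in newborn larvae, 211 had non-CG levels over 5% within 50 bases.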
